A study of Mus musculus with 6 samples.

How the data were processed

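The material was lumbar spinal cord, segments L4 to L5, of wild-type mice injected intrathecally with saline or with morphine (10 µg in 10 µL) for 7 days, per the labels. There were 3 saline and 3 morphine libraries, numbered as in the sample titles. The sample descriptions list runs of numbers, and whether a library pooled several animals is not given in the sources used here. Total RNA was extracted with PureLink and Trizol and made into libraries with the KAPA stranded RNA-Seq kit, per the labels. Per the submitters' processing notes, bcl2fastq 2.19.0, Trimmomatic, STAR, RSEM and the mm10 build were used. The versions of the last 3 tools, the annotation release and the use of strand in counting are not given in the sources used here.

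The deposited table holds FPKM values made by the authors, with 2 decimals, for 52513 Ensembl gene identifiers in 6 columns whose names match the sample descriptions. The symbols came from the table, and coordinates, biotypes, lengths and overlapping genes came from GENCODE M21 on the same build, which held 14588 of the 14614 tested genes (99.8%). Exonic length is the union of a gene's annotated exons. The columns were not rescaled for the main result, and their totals were 664464, 670280 and 662470 FPKM in saline and 741145, 722161 and 720234 FPKM in morphine.

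The depth was estimated from the table itself. A gene with few fragments can take only FPKM values that are whole multiples of 1 fragment, so the depth and mean fragment length were found at which the values of genes with 1 annotated transcript of 300 to 1500 nt and up to 6 fragments lay closest to whole numbers. At the estimates, 81.0% to 85.2% of these values were within 0.05 of a whole number of fragments, or within the rounding of the table where that is wider, against 12.9% to 15.3% for values spread evenly, and the mean fragment length came to 215 to 222 nt. Tested on simulated data, the depth of 2 simulated libraries was recovered within 0.16%. These were drawn as whole fragment counts with the same length formula that the estimate uses. The 0.16% therefore does not measure the error of the estimates for the real libraries. The fragments of Trpc5 and their 95% Poisson intervals follow from these estimates and from the longest transcript, and the pooled fragments were compared by an exact conditional test.

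Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested. Values were taken as log2(FPKM + 1), so all log2 fold changes are on that scale and are smaller than the ratio of means for genes near 1 FPKM. Morphine was compared with saline in limma 3.58.1 (R 4.3.3) with an intensity trend in the moderated variances, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Trpc5 and other study genes under the filter were read from the same model fitted without the filter. Trpc5 and Ezh2 also had an exact two-sided permutation test of their FPKM values, whose smallest p with 3 against 3 libraries is 0.1. Intervals, tests and plots beyond R used Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

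The 50 lists of genes were written before the data were examined, as were the model, the filter, the thresholds, the first set of other settings and the rule for named genes. They cover the chromatin, TRP channel and opioid genes of the study, neuronal transmission, stress and metabolism, immunity, and markers of the cell types a cord dissection could hold. The 42 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with a correlation estimated per list and fry were run as alternatives. Members were also counted by limma's adjusted p over all genes and adjusted over the list alone.

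Named genes are Ezh2 and Trpc5, the 12 genes with the largest fold in each direction among those past the threshold whose groups do not overlap, and from each list up to 4 members that passed, or up to 2 with the smallest p where none did. For lists of cell types, sample checks and RNA quality the rule adds up to 3 members with the highest mean. Genes without a symbol, predicted genes, clone names and pseudogenes count in the totals (65 of the 220 calls) but were not named. The names outside this rule were chosen after their values were seen: Eed, Suz12, the TRP genes other than Trpm3 and Trpc5, Trpc5os, Oprm1, Oprd1, Sdha, Rbm3, Malat1, Xist, Ttr and Acta1. Cirbp was fixed as a test before its value was seen.

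The main test was tried on simulated data with the spread of the real libraries, 14614 genes, 200 changed genes and 5 simulations. It recovered 52.8% of genes changed 1.5-fold, 80% of those changed 2-fold and 93.3% of those changed 3-fold, and 4.80% of its calls were false. These simulated libraries held no length trend, no scaling shift and no structure shared between genes. The 4.80% therefore does not carry over to the real calls, and another split of the real libraries gave 105 genes. With no effect, camera called a mean of 0.2 lists per run, but the simulated genes varied independently of each other. Where genes vary together this rate does not hold, and the 9 other splits of the real libraries into 3 and 3 gave 8 to 30 lists at the same setting. In a simulation with a length trend, the slope was -0.10 before and -0.00196 after its removal.

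The first set of other settings held a pseudocount of 0.1 or 0.5, no filter or a filter at a mean of 5 FPKM, median scaling, quantile normalization, rescaling to TPM, the replicate number as a block, limma without the intensity trend, limma with array weights, a fold of at least 1.5, each library left out in turn, and the other list tests. Added after the data were seen were the removal of a lowess trend (span 0.3) on length or on length and GC content, the myelin or motor neuron marker level as a covariate, leaving out saline 3 and morphine 2 together, and a filter at a mean of 0.5 FPKM. Lists matched on length or GC content and level were drawn 10000 times, each member being replaced by 1 of the 50 nearest genes.

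Mitochondrially encoded genes were not analysed here, since the table holds 1 entry matched by that list, the nuclear pseudogene Gm10925. The most abundant entries are annotated as nuclear pseudogenes of mitochondrial origin. Whether their fragments came from the nuclear copies or from mitochondrial RNA was not tested. Gm10925 was at 26242 ± 1057 FPKM in saline and 32985 ± 2141 in morphine (SD, n = 3 each), though not every such entry was higher in morphine. The 10 highest genes took 24.8%, 26.2% and 23.9% of the total in saline 1, 2 and 3. They took 28.0%, 27.8% and 25.8% in morphine 1, 2 and 3. Raw reads were not analysed here, and the values of some genes are not reported here.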

Results

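RNA was measured in the lumbar spinal cord, segments L4 to L5, of wild-type mice that received intrathecal injections of saline or of morphine (10 µg in 10 µL) for 7 days. There were 3 libraries per group, all from total RNA with a stranded kit. The table used here gives FPKM values (fragments scaled to transcript length and to the library's mapped fragments) for 52513 genes, of which 28021 were above 0 in at least 1 library. The depth is not given in the sources used here, and it was estimated from the steps that low FPKM values take. It came to 21.5, 26.1 and 21.4 M fragments in saline 1, 2 and 3, and to 19.9, 17.9 and 18.6 M in morphine 1, 2 and 3. Between 22754 and 23492 genes were above 0 per library.

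Sex, segment and tissue markers were alike across the libraries. Xist, the RNA that coats the inactive X of females, was at 0.01 FPKM or less in all 6 libraries, and the Y-linked helicase gene Ddx3y lay between 26.3 and 29.4 FPKM, so all 6 libraries had a male profile. Hoxc10, a homeobox gene of lumbar segments, was at 59.0 ± 5.67 FPKM in saline and 56.1 ± 5.17 in morphine (SD, n = 3 each), and Ttr, the choroid plexus carrier of thyroid hormone, was at 0.15 FPKM or less. The most abundant protein-coding transcript was Mbp, a myelin protein, at 10687 ± 2150 FPKM in saline and 11301 ± 1723 in morphine (SD, n = 3 each). Pearson's r between libraries, across genes that are not independent replicates, ran from 0.978 to 0.990. The first principal component held 37.2% of the variance. Saline 1, 2 and 3 scored -19.2, -16.3 and -4.81 on it, and morphine 1, 2 and 3 scored 20.8, -3.16 and 22.7.

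Markers of motor neurons differed between libraries within each group. Slc5a7, the choline transporter of cholinergic neurons, was at 22.9, 20.4 and 3.70 FPKM in saline 1, 2 and 3 and at 4.62, 18.3 and 1.86 in morphine 1, 2 and 3. Chodl, a marker of fast motor neurons, ran in parallel at 31.5, 29.5 and 4.99 FPKM in saline and 8.89, 25.1 and 2.83 in morphine. The mean log2 level of the motor and cholinergic neuron list was 4.03, 3.86 and 2.42 in saline and 2.81, 3.89 and 2.10 in morphine. Thus saline 1, saline 2 and morphine 2 held more motor neuron marker RNA than saline 3, morphine 1 and morphine 3, which is 2 libraries of 1 group against 1 of the other.

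The comparison of morphine with saline asks which transcripts differ in the cord after a morphine course that the series title links to tolerance, and in particular what became of Trpc5 and Ezh2, the genes the title names. Trpc5, a calcium-permeable cation channel of neurons, was 2.31-fold lower after morphine, at 0.80 ± 0.217 FPKM in saline and 0.347 ± 0.0451 in morphine (SD, n = 3 each). Its 3 morphine values (0.39, 0.35 and 0.30 FPKM) all lay below its 3 saline values (0.68, 0.67 and 1.05 FPKM). Groups that did not overlap, in either direction, were found in 28.7% of tested genes. Trpc5 was under the level set for testing and, fitted without that filter, did not pass (limma adjusted p = 0.151). Ezh2, the enzyme of Polycomb repressive complex 2 (PRC2) that methylates histone H3 at lysine 27, was at 6.38 ± 0.714 FPKM in saline and 7.44 ± 0.747 in morphine (SD, n = 3 each), and did not pass the test. Across the transcriptome 138 genes rose and 82 fell at an adjusted p under 0.05. Lists of heat shock, endoplasmic reticulum (ER) chaperone and immediate early genes fell, with Hspa1b 4.99-fold and Fos 2.14-fold lower, while lists of ribosomal protein and oxidative phosphorylation genes rose by medians of 0.31 and 0.24 in log2 units, which were 0.18 and 0.11 with the values rescaled to transcripts per 1e6 (TPM) and 0.15 and 0.10 after quantile normalization. These lists passed camera's test with its preset correlation and not with an estimated correlation (adjusted p = 0.161 for the ER list and adjusted p = 0.339 for each of the others).

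Trpc5 (ENSMUSG00000041710) lies on chromosome X from 144381671 to 144688180 on the minus strand of mm10, and the annotation gives it 2 transcripts of 2782 and 4158 nt with up to 11 exons. It was below the level set for testing, 1 FPKM in 3 libraries. Fitted with no filter, its log2 fold change on the log2(FPKM + 1) scale was -0.41 (SE 0.10, 95% interval -0.66 to -0.17), with a limma p of 0.00590 and an adjusted p of 0.151. The exact two-sided permutation test of the FPKM values gave p = 0.1, the smallest that 3 against 3 allows. The value corresponded to about 58, 69 and 88 fragments in saline 1, 2 and 3 and to 31, 25 and 22 in morphine 1, 2 and 3. The 95% Poisson interval was widest in relative terms in morphine 3, from 13.8 to 33.3 fragments, and intervals of this kind cover counting error alone. Pooled by group, 215 fragments against 78 gave a rate ratio of 0.444 (95% interval 0.338 to 0.577). Trpc5os, a gene on the opposite strand within the Trpc5 locus that shares no exonic sequence with it, was at 0.02 FPKM or less in every library.

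Ezh2 (ENSMUSG00000029687) lies on chromosome 6 from 47530139 to 47595341 on the minus strand and overlaps the antisense gene Gm26625. Its log2 fold change was 0.19 (SE 0.11), with a limma adjusted p of 0.328 and an exact permutation p of 0.2. Of the list of 14 PRC2 genes and H3K27 demethylases, 13 were tested and 0 passed limma's test, over all genes or adjusted over the list alone, and Kdm6a, Rbbp4 and Eed were the 3 among them with an unadjusted p under 0.05. Kdm6a, the X-linked demethylase that removes the mark Ezh2 writes, was at 6.10 ± 0.512 FPKM in saline and 4.52 ± 0.344 in morphine (log2 fold change -0.36, adjusted p = 0.0825). Rbbp4, a histone-binding subunit of PRC2, was at 50.8 ± 2.69 and 60.1 ± 4.06 FPKM (adjusted p = 0.112). The core subunits Eed and Suz12 were at 12.2 and 10.8 FPKM in saline and at 14.3 and 9.82 FPKM in morphine. The median of the list was 0.03 and its sign turned when the libraries were rescaled to TPM.

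Among TRP channels 9 of 26 listed genes were expressed well enough for the test, and 1 of them fell, over all genes and adjusted over the list alone. This was Trpm3, a channel gated by heat and by pregnenolone sulphate, which decreased from 5.06 ± 0.311 to 3.17 ± 0.206 FPKM (SD, n = 3 each; log2 fold change -0.54, adjusted p = 0.0462). Trpc1, a subunit that can join Trpc5 in one channel, was at 7.03 and 6.64 FPKM. Trpc4, the nearest relative of Trpc5, stayed under the test's level at 0.757 and 0.667 FPKM, as did Trpc6 and Trpc7. Trpv1 and Trpa1, channels of nociceptors, were at 0.12 FPKM or less on average in both groups.

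The opioid genes did not pass the test. Pomc, the precursor of beta-endorphin, was at 1.57 ± 0.425 FPKM in saline and 2.30 ± 0.250 in morphine (SD, n = 3 each; adjusted p = 0.192), and Oprk1, the kappa receptor, was at 3.50 and 3.89 FPKM. Of 6 tested receptor and peptide genes and 31 tested genes of receptor signalling, 0 passed over all genes and 0 adjusted over the list alone in limma's test, with 1 and 3 at an unadjusted p under 0.05. The smallest p values among signalling genes belonged to Adcy5, an adenylyl cyclase, at 16.3 and 14.3 FPKM (adjusted p = 0.144), and Creb1, a transcription factor that answers cyclic AMP, at 7.71 and 6.57 FPKM (adjusted p = 0.217). Oprm1 and Oprd1, the mu and delta receptors, were under the test's level. Oprm1 was at 0.597 ± 0.0874 and 0.357 ± 0.225 FPKM, and Oprd1 was at 0.820 ± 0.156 and 0.340 ± 0.0346 FPKM (unfiltered log2 fold change -0.44, adjusted p = 0.114).

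Of 14614 genes tested with limma, 220 changed, and 155 of these were protein coding (89 higher, 66 lower). At an unadjusted p under 0.05 there were 1643 higher and 1618 lower. In 4191 tested genes (28.7%) the 3 values of one group all lay above those of the other, where chance gives 10%. The direction of the calls depended on the scaling between libraries: quantile normalization gave 47 higher and 55 lower, and rescaling to TPM, which moves the median log2 fold change of all genes from -0.02 to -0.13, gave 101 higher and 853 lower. The number also rested on single libraries, since 1 gene passed without saline 1, 8 without saline 2, 2 without saline 3, 1 without morphine 1, 805 without morphine 2 and 1 without morphine 3. Fold changes became more negative with the length of the transcript (Spearman's rho -0.310 across 14588 genes, which are not independent replicates), and 34 of the 220 genes passed once that trend was removed.

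The largest fall was that of Mir6236, annotated as a microRNA precursor of 123 nt on chromosome 9 (110281287 to 110281409), which was at 23.1, 19.7 and 24.9 FPKM in saline and listed at 0 in all 3 morphine libraries. The annotated gene is shorter than the mean fragment, estimated at 215 to 222 nt, so its FPKM rests on an uncertain length. Why the value was 0 in all 3 morphine libraries was not tested, so the fall is uncertain as a measure of this RNA. Hspa1b and Hspa1a, the inducible cytosolic Hsp70 chaperones on chromosome 17, fell 4.99-fold and 6.74-fold. Hspa1b went from 19.9 ± 5.23 to 3.99 ± 0.492 FPKM and Hspa1a from 8.78 ± 3.26 to 1.30 ± 0.0777 FPKM (SD, n = 3 each; limma adjusted p = 0.0149 and 0.0361). The 2 genes are near-identical copies, so the division of fragments between them is uncertain. Fos, the classical marker of recent neuronal activity (chromosome 12, 85473890 to 85477273), fell from 22.6 ± 1.32 to 10.6 ± 1.78 FPKM (SD, n = 3 each; log2 fold change -1.04, SE 0.12, adjusted p = 0.0361). Hbb-bt, a beta-globin of red cells, fell from 65.9 ± 14.7 to 27.9 ± 4.24 FPKM (adjusted p = 0.0453).

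Kcnk9, the two-pore potassium channel TASK-3 that sets the resting potential (chromosome 15, 72501089 to 72546340), fell 5.10-fold from 6.06 ± 1.19 to 1.19 ± 0.837 FPKM (SD, n = 3 each; log2 fold change -1.74, SE 0.26, limma adjusted p = 0.0456). Gabrb2, the beta-2 subunit of GABA-A receptors (chromosome 11, 42419757 to 42629028), fell 3.16-fold from 3.13 ± 0.50 to 0.990 ± 0.227 FPKM (adjusted p = 0.0434). Atp2b3, a plasma membrane calcium pump of neurons, fell from 11.6 ± 1.94 to 5.33 ± 0.733 FPKM, and Adcy9, an adenylyl cyclase, fell from 4.46 ± 0.514 to 1.89 ± 0.134 FPKM (adjusted p = 0.0453 and 0.0365). Lmbrd2, a membrane protein, fell from 2.14 to 0.817 FPKM (adjusted p = 0.0463). Moap1, a regulator of apoptosis, fell from 15.1 to 7.60 FPKM (adjusted p = 0.0484) but overlaps the gene Gm20604 on the same strand. Pcdhgc3, a clustered protocadherin of neuronal recognition, fell from 14.9 to 7.81 FPKM (adjusted p = 0.0456) and shares exons with other protocadherin gamma genes. How fragments were shared between such overlapping genes, and whether strand was used in counting, is not given in the sources used here.

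**Figure D1:**
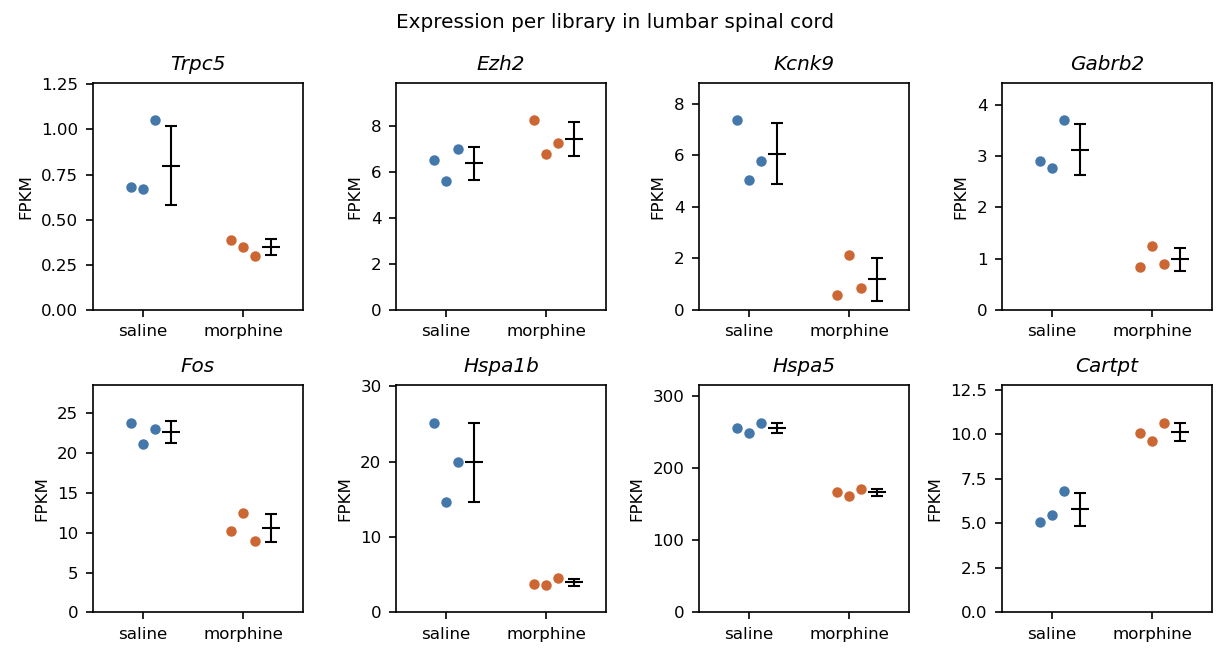
FPKM of 8 genes in the 3 saline and 3 morphine libraries, each point a library and each bar the mean with its SD, on axes that start at 0. Trpc5, Kcnk9, Gabrb2, Fos, Hspa1b and Hspa5 have all 3 morphine values below all 3 saline values, Cartpt (5.79 against 10.1 FPKM) has them above, and the groups overlap for Ezh2.

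Cartpt, the precursor of the CART neuropeptides (chromosome 13, 99898489 to 99901091), rose from 5.79 ± 0.923 to 10.1 ± 0.497 FPKM (SD, n = 3 each; log2 fold change 0.72, SE 0.11, limma adjusted p = 0.0456). Acot13, a mitochondrial acyl-CoA thioesterase, rose 1.53-fold from 75.5 ± 1.98 to 116 ± 3.13 FPKM (adjusted p = 0.0141). Acbd7, which carries an acyl-CoA binding domain, rose from 1.36 to 2.5 FPKM, and Pxmp2, a channel of the peroxisomal membrane, rose from 4.69 to 7.81 FPKM (adjusted p = 0.0476 and 0.0463). Rpgrip1, a protein of the photoreceptor cilium (chromosome 14, 52110704 to 52163546), rose 15.1-fold from 0.483 ± 0.146 to 7.30 ± 2.85 FPKM (adjusted p = 0.0361) and overlaps Supt16 on the opposite strand. Dnah14, an axonemal dynein heavy chain, rose from 14.3 ± 0.817 to 25.8 ± 0.736 FPKM (adjusted p = 0.0141) and lies opposite Lbr. Gdf1, a growth factor of the TGF-beta family, rose from 11.4 to 20.2 FPKM (adjusted p = 0.0462) and overlaps Cers1 on the same strand. These 3 values are therefore uncertain as measures of the named gene.

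Izumo4, a relative of the sperm protein Izumo1, rose from 14.8 to 24.1 FPKM, and Nemp2, a protein of the inner nuclear membrane, rose from 1.70 to 3.29 FPKM (n = 3 each; limma adjusted p = 0.0453 and 0.0462). Isoc2b, a protein with an isochorismatase domain, rose from 1.58 to 3.23 FPKM (adjusted p = 0.0462). Ccdc153, a gene of motile cilia, rose from 0.240 to 1.48 FPKM (adjusted p = 0.0488). Rnu2-10, a copy of the U2 spliceosomal RNA, rose from 0.26 to 1.6 FPKM (adjusted p = 0.0465). It is 191 nt long, shorter than the mean fragment, and 4 U2 copies carry the same values in every library, so it counts as 1 measurement. Of the 220 genes, 1 (Mir6236) still passed without saline 1, without saline 3, without morphine 1 or without morphine 3, 6 passed without saline 2 and 219 without morphine 2.

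Of 42 lists of genes with at least 5 tested members, camera with its preset correlation of 0.01 called 12, of which 3 rose and 9 fell. With a correlation estimated for each list, camera called 0, with 6 lists at an unadjusted p under 0.05, and fry, which asks whether the members of a list move one way on balance, called 6 (heat shock, ER chaperone, immediate early, ribosomal, oxidative phosphorylation and ependymal). The medians of the 12 lists kept their sign under each scaling that was tried, though not their size.

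**Figure D2:**
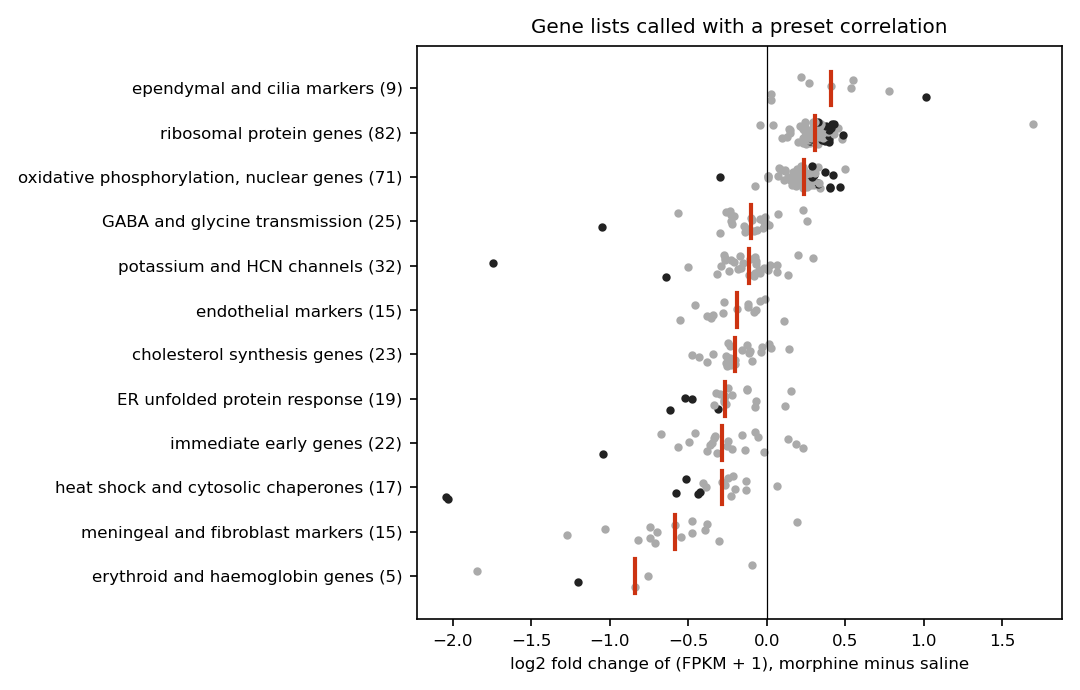
Log2 fold change, morphine minus saline on the log2(FPKM + 1) scale, of each tested gene in the 12 called lists. Points are genes, dark where they passed over all genes tested and grey elsewhere, and the red line is the median, which ran from -0.84 in the erythroid list to 0.41 in the ependymal list and kept its sign under every scaling tried.

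Heat shock and cytosolic chaperone genes fell as a list, with 16 of 17 members lower and a median log2 fold change of -0.29 (camera adjusted p = 1.64e-09, adjusted p = 0.339 with an estimated correlation). By limma, 6 members fell over all genes and 13 adjusted over the list alone. Besides the Hsp70 genes these included Dnajb1, the Hsp40 partner of Hsp70, from 28.6 ± 2.04 to 18.8 ± 0.255 FPKM (adjusted p = 0.0375), and Chordc1, a cochaperone of Hsp90, from 29.0 ± 1.33 to 20.1 ± 0.993 FPKM (SD, n = 3 each; adjusted p = 0.0434). Rbm3, a cold-induced RNA-binding protein chosen after its values were seen, rose from 138 ± 10.3 to 203 ± 7.15 FPKM (adjusted p = 0.0391).

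The ER unfolded protein response list fell likewise, with 17 of 19 members lower and a median of -0.26 (camera adjusted p = 3.20e-07, adjusted p = 0.161 with an estimated correlation). By limma, 4 members fell over all genes and 13 adjusted over the list alone. Hspa5, the main Hsp70 chaperone of the ER lumen, fell from 256 ± 6.92 to 167 ± 4.92 FPKM (SD, n = 3 each; log2 fold change -0.62, SE 0.05, adjusted p = 0.0141). Pdia4, a disulphide isomerase, and Sdf2l1, a partner of Hspa5, fell from 26.1 to 17.8 FPKM and from 29.2 to 20.7 FPKM (adjusted p = 0.0375 and 0.0434). Xbp1, the transcription factor of the response, was at 56.3 and 44.3 FPKM and passed over the list alone (adjusted p = 0.0167; 0.0907 over all genes).

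Immediate early genes, which neurons transcribe within minutes of activity, fell as a list, with 19 of 22 members lower and a median of -0.28 (camera adjusted p = 2.95e-04, adjusted p = 0.339 with an estimated correlation). By limma, Fos was the 1 member that fell over all genes, while adjusted over the list alone 10 fell and 1 rose. Egr1, an activity-induced zinc finger factor, fell over the list alone from 19.5 ± 2.46 to 12.8 ± 0.992 FPKM (SD, n = 3 each; adjusted p = 0.00943, and 0.0509 over all genes). Klf2 and Nr4a3, transcription factors of the same class, fell over the list alone, from 7.64 to 4.55 FPKM and from 1.30 to 0.627 FPKM (adjusted p = 0.0208 and 0.0204).

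Ribosomal protein genes rose as a list, with 81 of 82 members higher and a median of 0.31 (camera adjusted p = 6.70e-37, adjusted p = 0.339 with an estimated correlation). By limma, 16 members rose over all genes and 74 adjusted over the list alone. Rps19, of the small subunit, rose from 257 ± 16.3 to 360 ± 34.9 FPKM and Rpl13a, of the large subunit, from 797 ± 22.8 to 1071 ± 48.5 FPKM (SD, n = 3 each; adjusted p = 0.0465 and 0.0427). Nuclear genes of oxidative phosphorylation rose too, with 69 of 71 members higher and a median of 0.24 (camera adjusted p = 5.31e-27, adjusted p = 0.339 with an estimated correlation). By limma, 12 rose and 1 fell over all genes, and 59 rose and 1 fell adjusted over the list alone. Ndufa5 and Ndufa6, subunits of complex I, rose from 343 to 475 FPKM and from 344 to 456 FPKM, and Uqcrq of complex III rose from 322 to 432 FPKM (adjusted p = 0.0465, 0.0456 and 0.0456). The gene that fell was Sdha, a subunit of complex II, from 201 to 164 FPKM (adjusted p = 0.0465). The ribosomal median was 0.15 after quantile normalization and 0.18 in TPM, and that of oxidative phosphorylation 0.10 and 0.11.

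Transcript length moved with the group beside these lists. With the genes split by exonic length into 10 bins of equal size, the median log2 fold change went from 0.17 at 708 nt to -0.09 at 12345 nt. Lists matched to the ribosomal genes on length and level had a median of 0.15 (95% range 0.11 to 0.21) against 0.31 for the ribosomal genes. Lists matched to the oxidative phosphorylation genes had a median of 0.19 (0.14 to 0.24) against 0.24.

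**Figure D3:**
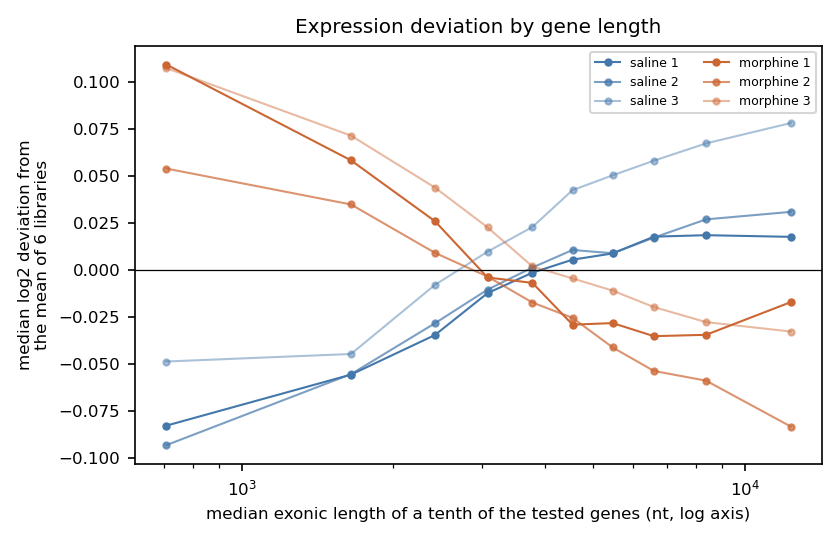
Median deviation of each library from the mean of all 6 libraries, in log2 units, in 10 bins of the tested genes by exonic length (nt, log axis), with 1 line per library. In the shortest bin (708 nt) the 3 saline lines lie between -0.09 and -0.05 and the 3 morphine lines between 0.05 and 0.11, and in the longest bin (12345 nt) the saline lines lie above the morphine lines.

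Potassium and HCN channel genes fell as a list, with 25 of 32 members lower and a median of -0.11 (camera adjusted p = 0.00294, adjusted p = 0.763 with an estimated correlation). By limma, Kcnk9 and Kcna1 fell over all genes and 5 members fell adjusted over the list alone. Kcna1, the Kv1.1 channel of axons, fell from 17.1 ± 0.806 to 10.6 ± 1.04 FPKM (SD, n = 3 each; adjusted p = 0.0434). Kcnj10, the Kir4.1 channel of astrocytes and oligodendrocytes, fell over the list alone from 167 ± 6.44 to 119 ± 16.7 FPKM (adjusted p = 0.0122, and 0.0567 over all genes). Genes of GABA and glycine transmission fell as a list, with 21 of 25 members lower and a median of -0.10 (camera adjusted p = 0.0269, adjusted p = 0.984 with an estimated correlation). By limma, Gabrb2 fell over all genes and 3 members fell adjusted over the list alone, among them Slc6a5, the glycine transporter of glycinergic neurons, from 55.9 ± 7.32 to 37.3 ± 3.84 FPKM (adjusted p = 0.0196) and Slc6a11, a GABA transporter of astrocytes, from 96.3 to 81.9 FPKM (adjusted p = 0.0374). Removing the length trend ended both calls, at an adjusted p of 0.0551 for the channels (range over the alternatives 3.78e-04 to 0.763) and 0.201 for GABA and glycine (range 3.50e-05 to 0.993). Leaving out saline 3 and morphine 2 together ended both calls too, at an adjusted p of 0.127 for the channels and 0.993 for GABA and glycine, whose median turned to 0.04. The GABA and glycine call was also lost without saline 3 alone (median -0.03, adjusted p = 0.195) and without morphine 2 alone (median -0.05, adjusted p = 0.278), and its median was -0.16 without saline 1 or without morphine 3.

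Other neuronal lists were not called. Among glutamate receptors, Grin2b, an NMDA receptor subunit, rose from 1.78 to 3.49 FPKM and Gria4, an AMPA receptor subunit, fell from 52.8 to 41.0 FPKM adjusted over the list alone (limma adjusted p = 0.0415 and 0.0328, and 0.0708 and 0.0557 over all genes). Syt2, a fast calcium sensor of synaptic vesicles, was the 1 of 22 release genes that fell adjusted over the list alone, from 70.2 to 48.0 FPKM (adjusted p = 0.0255, and 0.0542 over all genes). Dorsal horn neuropeptides and their receptors held 0 of 21 genes that passed limma's test, over all genes or adjusted over the list alone, and 1 at an unadjusted p under 0.05. This was Nmb, neuromedin B, at 5.6 and 8.34 FPKM (adjusted p = 0.154). Their median of 0.08 turned sign under TPM. Of 24 sodium and calcium channel genes 0 passed limma's test and 4 had an unadjusted p under 0.05, with the smallest p at Scn1a, the Nav1.1 channel (48.2 and 41.2 FPKM, adjusted p = 0.111). Their median of -0.01 turned sign under median scaling and quantile normalization.

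Genes of cholesterol synthesis fell as a list by camera, with 20 of 23 members lower and a median of -0.20 (adjusted p = 0.00189, adjusted p = 0.984 with an estimated correlation), though 0 members passed limma's test over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05. Without saline 1 the median was -0.12 and the camera adjusted p 0.0619 (range over the alternatives 7.21e-09 to 0.984). The smallest p values belonged to Cyp51, the lanosterol demethylase, at 73.4 and 56.0 FPKM, and Sc5d, a late desaturase of the pathway, at 39.6 and 29.2 FPKM (limma adjusted p = 0.0794 and 0.0871). Glucocorticoid-responsive genes were not called (median 0.17), but 4 of 18 rose adjusted over the list alone. They were Plin4, a coat protein of lipid droplets, from 1.59 to 5.84 FPKM, Hif3a, a hypoxia factor, from 0.747 to 2.06 FPKM, and the metallothioneins Mt1, from 761 to 1190 FPKM, and Mt2, from 404 to 617 FPKM (adjusted p = 0.0180, 0.0345, 0.0319 and 0.0345). Over all genes their adjusted p ran from 0.0532 to 0.0929. Among NRF2 targets, Gstm1, a glutathione transferase, rose from 122 to 167 FPKM and Gpx4, which reduces lipid peroxides, rose from 483 to 606 FPKM (adjusted p = 0.0465 and 0.0462). In TPM, Gstm1 passed and Gpx4 did not (limma adjusted p = 0.0424 and 0.0752). In the same list Sod1 rose and Txnrd1 fell adjusted over the list alone. Hdac3, a deacetylase in the list of other chromatin-modifying enzymes, rose adjusted over the list alone from 42.7 ± 0.741 to 53.7 ± 3.27 FPKM (adjusted p = 0.0277, and 0.0548 over all genes), the 1 of 22 that passed.

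Among lists of cell types, ependymal and cilia markers rose, with 9 of 9 members higher and a median of 0.41 (camera adjusted p = 0.00189, adjusted p = 0.339 with an estimated correlation). By limma, Ccdc153 rose over all genes, and Dynlrb2 and Enkur, also genes of cilia, rose with it over the list alone, from 0.593 to 1.77 FPKM and from 0.490 to 1.18 FPKM (adjusted p = 0.0168 each). Foxj1, the master factor of motile cilia, was at 9.67 and 9.85 FPKM. Red cell genes fell, with 5 of 5 members lower and a median of -0.84 (camera adjusted p = 0.00189, adjusted p = 0.763 with an estimated correlation). With no filter, which adds members near 0 FPKM, the median was -0.09 and camera still called the list. By limma, Hbb-bt fell over all genes and 4 globins fell adjusted over the list alone, including Hba-a1 from 392 ± 73.8 to 231 ± 31.9 FPKM and Hbb-bs from 420 ± 71.2 to 236 ± 53.9 FPKM (SD, n = 3 each; adjusted p = 0.00320 each). The globin genes are similar in sequence, and the division of fragments between copies is uncertain. Neutrophil and monocyte genes, too few to be tested as a list, had 4 of 4 members lower and a median of -0.55.

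Vascular and meningeal markers were called lower by camera. Meningeal and fibroblast markers had 14 of 15 members lower and a median of -0.59 (adjusted p = 0.00559, adjusted p = 0.984 with an estimated correlation), and 0 passed limma's test over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. Igf2, a growth factor of the meninges, was at 49.2 ± 15.7 and 24.0 ± 17.5 FPKM (SD, n = 3 each). The mean log2 level of the list was 3.96, 3.57 and 3.56 in saline and 3.16, 3.78 and 2.35 in morphine, so that morphine 2 lay above saline 2 and 3. Endothelial markers had 14 of 15 members lower and a median of -0.19 (adjusted p = 0.00965, adjusted p = 0.984 with an estimated correlation). Pecam1, an adhesion molecule of endothelium, fell adjusted over the list alone from 5.20 ± 0.101 to 3.25 ± 0.581 FPKM (adjusted p = 0.0256, and 0.0589 over all genes). With the motor neuron marker level as a covariate, a setting added after the data were seen, camera gave the meningeal list an adjusted p of 0.0611 (range over the alternatives 4.96e-06 to 0.984) and the endothelial list 0.147 (range 1.43e-05 to 0.984). The meningeal list also lost its call without saline 1 (0.0614), without morphine 3 (0.186) and under TPM (0.143), and the endothelial list without saline 2 (0.0665), morphine 1 (0.0731) or morphine 3 (0.0867). The meningeal median was -0.27 without morphine 3 and -0.85 without morphine 2, and the endothelial median was -0.12 without morphine 1 and -0.33 without morphine 2.

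Pan-neuronal markers had a median of 0.01 that turned sign under quantile normalization and TPM, with Snap25, a protein of synaptic release, at 1618 ± 158 and 1643 ± 115 FPKM (SD, n = 3 each), and 0 of 18 passed limma's test, with 5 at an unadjusted p under 0.05. The medians of microglia, astrocyte and oligodendrocyte markers were -0.07, -0.07 and -0.04. Ctss, a protease of microglia, was at 105 and 102 FPKM. Among astrocyte markers Sox9, a transcription factor of the lineage, rose from 5.32 ± 0.129 to 7.84 ± 0.546 FPKM (adjusted p = 0.0463), and Aldoc, an aldolase, rose over the list alone from 912 to 1053 FPKM (adjusted p = 0.0247). The log2 fold change of Aldoc depended on the scaling, at 0.21 as deposited, 0.08 in TPM and 0.003 after quantile normalization. Gpr17, a receptor of differentiating oligodendrocyte precursors, fell over the list alone from 18.7 to 12.2 FPKM (adjusted p = 0.0373). Kcnj8 and Rgs5, of pericytes, fell over the list alone, from 1.99 to 1.15 FPKM and from 34.7 to 29.0 FPKM (adjusted p = 0.0459 each). Il18, an interleukin of the inflammasome pathway, rose from 37.6 ± 1.15 to 48.3 ± 2.08 FPKM (SD, n = 3 each; adjusted p = 0.0465), the 1 of 14 tested cytokine and Toll-like receptor genes that passed. Pvalb, listed with skeletal muscle and also made by interneurons, rose from 100.2 to 125 FPKM (adjusted p = 0.0495), while the muscle actin Acta1 was at 1.09 and 1.26 FPKM. In TPM, Il18 and Pvalb did not pass (limma adjusted p = 0.0653 and 0.0731).

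Other lists that were not called are given by their medians, which were -0.25 for pericyte markers, -0.53 for motor and cholinergic neuron markers, -0.17 for Schwann cell and nerve root markers and -0.21 for reactive astrocyte genes. They were -0.04 for oligodendrocyte precursor markers, -0.12 for complement genes, -0.03 for clock genes, -0.03 for cell cycle genes, -0.03 for extracellular matrix genes and -0.03 for replication-dependent histone genes. Interferon-stimulated and antigen presentation genes had medians within 0.01 of 0 that turned sign under median scaling and quantile normalization, lumbar Hox genes had 0.02 and dorsal horn neuron markers 0.07, both of which turned under TPM. In lists with fewer than 5 tested members, S100a8 of neutrophils and Ighm of B cells fell adjusted over the list alone, from 2.08 to 0.747 FPKM and from 5.83 to 4.24 FPKM (limma adjusted p = 0.0237 and 0.0452, and 0.0845 and 0.154 over all genes). The median was 0.15 over 3 dorsal root ganglion neuron markers, -0.24 over 4 perivascular macrophage genes, 0.36 over 4 skeletal muscle genes, 0.02 over 4 markers of choroid plexus and brain regions and -0.01 over 2 lymphocyte genes. The last 2 of these turned sign under at least 1 other scaling.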

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

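The length, GC, covariate, joint leave-out and 0.5 FPKM filter settings were chosen after the data were seen, and so was rescaling to TPM for the lists. Trpc5 kept its sign in 20 alternatives (log2 fold change -0.99 to -0.32, adjusted p 0.0974 to 0.326), as did Ezh2 in 22 (0.08 to 0.31, adjusted p 0.124 to 0.634), and neither passed in any. Against 220 genes as reported, 8 passed with no filter, 28 with a filter at a mean of 0.5 FPKM, 36 without the intensity trend, 34 with the length trend removed, 31 with length and GC trends removed, 102 after quantile normalization and 86 with a fold of at least 1.5. Counts were higher with median scaling (488), TPM (954), array weights (1467), a myelin covariate (1302), a motor neuron marker covariate (925) and without saline 3 and morphine 2 (1539). That last setting leaves motor neuron marker levels of 4.03 and 3.86 in saline against 2.81 and 2.10 in morphine, so it aligns them with the groups. The 2 covariates, array weights and median scaling kept all 220 genes. Leaving out 1 library gave 1 to 805 genes (805 without morphine 2, of which 219 are among the 220). Against 12 lists, 0 were called with an estimated correlation, 6 by fry and 22 without saline 3 and morphine 2; the other alternatives gave 10 to 17. The cause was not tested, except that the fold minimum selects among the same calls.

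With the replicate number as a replicate block, 24 genes passed (17 of them among the 220) and 13 lists were called. After removing group means, the correlations of saline 1, 2 and 3 with the morphine library of their number were -0.13, 0.16 and 0.29. Saline 2 and saline 3 correlated best with their own number, whereas saline 1 correlated best with morphine 2 (0.24). With 3 libraries per group these correlations cannot decide whether the numbers pair the libraries. Among the 12 lists and 41 genes that passed and were named by the rule, 669 results under an alternative stayed on their side of the threshold and 450 did not, with 0 reversals of the tested direction. The depth of 17.9 to 26.1 M fragments leaves Trpc5 with 22 to 88 fragments per library.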

Other observations

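The length tests on the ribosomal, oxidative phosphorylation and Trpc5 results, the myelin test, the motor neuron covariate and the counts over other splits of the libraries were chosen after the results were seen.

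Antisense genes, lincRNA genes and processed pseudogenes had higher medians than protein-coding genes. The median log2 fold change was 0.15 over 271 antisense genes, 0.12 over 283 lincRNA genes and 0.03 over 603 processed pseudogenes, against -0.02 over 12898 protein-coding genes. Short genes of all classes together also had higher medians (0.17 in the bin at 708 nt). The classes were not matched on length, so a difference by class cannot be told apart from the length trend. Of the 220 changed genes, 15 were antisense (14 higher, 1 lower), 25 were processed pseudogenes (15 higher, 10 lower) and 6 were lincRNAs (4 higher, 2 lower). Malat1, an abundant nuclear RNA, was at 426 ± 18.5 FPKM in saline and 577 ± 75.7 in morphine (SD, n = 3 each; limma adjusted p = 0.0644). The 15 tested small nuclear RNA genes hold 4 distinct sets of values, and the 4 U2 copies that rose share 1 set.

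Prph and Calca varied within groups, in parallel with the motor neuron markers. Of 14 listed markers of dorsal root ganglion neurons, 3 passed the filter, and the nociceptor channel Trpv1 was at 0.24 FPKM or less in every library. The values thus do not show a varying share of sensory neurons. Prph, an intermediate filament of motor and sensory neurons, was at 55.1, 53.7 and 8.98 FPKM in saline 1, 2 and 3 and 21.4, 55.6 and 7.03 in morphine 1, 2 and 3, and Calca, the CGRP precursor, was at 81.8, 113 and 23.5 FPKM and 50.5, 106 and 20.8.

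Genes of ribosomal proteins and of oxidative phosphorylation were higher after morphine, and short transcripts in general were higher relative to long ones. The median of the ribosomal list lay at percentile 100 of 10000 lists matched on exonic length and level. This argues against a trend with annotated exonic length as its whole cause. It does not cover a trend with the length of the expressed transcripts, which was not measured. Drawn genes were also picked singly, while the ribosomal genes vary together (estimated correlation 0.47), so the percentile overstates the certainty. The median of the oxidative phosphorylation list lay at percentile 97.19, within the range the length trend gives, so the trend stays open there. With the exonic length trend removed, the ribosomal and oxidative phosphorylation medians were 0.22 and 0.13. Camera with its preset correlation still called both lists (adjusted p = 7.5e-30 and 3.8e-14). Matching on GC content instead of length gave percentiles of at least 99.99, which argues against GC content, with the same limit of genes drawn singly. A larger share of myelin would lift oligodendrocyte markers, and a smaller share pan-neuronal markers, at least as far as the 2 lists. Their medians of -0.0354 (SE 0.0438) and 0.0103 (SE 0.0666) lay under 0.24. These SEs are over genes and leave out variation between libraries, so this comparison cannot decide on the share of myelin. The mean log2 level of the oligodendrocyte list was 8.27, 8.28 and 7.81 in saline 1, 2 and 3. It was 8.00, 8.36 and 7.94 in morphine 1, 2 and 3. The groups thus overlapped in this level, whereas both pathway lists were higher in every morphine library than in any saline library. A change in the 2 pathways after morphine stays open. An effect of RNA handling on short transcripts, which no label records, stays open for both lists.

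Heat shock, ER chaperone and immediate early genes were lower after morphine in all 3 libraries. Their medians lay at percentile 0 of 10000 lists matched on length and level (highest of the 3), which argues against the length trend. Heat shock genes follow temperature, and a cooler tissue is a candidate explanation. The cold-inducible gene Cirbp, fixed as the test beforehand, had a log2 fold change of 0.42 with a limma adjusted p of 0.0954. Its unadjusted p was under 0.05, the level set for the test, which is the result a cooler tissue predicts. However, 1643 of 14614 tested genes were higher at that level, so the test is easily passed and cannot single out temperature. In TPM the log2 fold change of Cirbp was 0.29 (limma adjusted p = 0.126). This leaves open whether morphine lowered body temperature or neuronal activity, or whether the animals or tissue were handled differently, since no label gives temperature, time or order of dissection.

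Trpc5 was lower in all 3 morphine libraries. Counting noise alone is argued against by the pooled fragments (exact p = 1.39e-10), which treats the fragments as independent and leaves out variation between animals. Among the 500 genes nearest in length and level, which carry that variation too, its log2 fold change of -0.41 lay at percentile 2.2, just beyond the 2.5th percentile of -0.39. The length trend as its whole cause is argued against by the log2 fold change of -0.38 with the trend removed (SE 0.10, 95% interval -0.61 to -0.15; adjusted p = 0.174). A lower share of neurons is argued against by the pan-neuronal median of 0.0103 (SE 0.0666, negative under quantile normalization and TPM). That SE is over genes and leaves out variation between libraries, in which the list's mean log2 level ran from 8.01 to 8.11. The median does not cover the loss of a single neuron type. With the motor neuron marker level as a covariate the log2 fold change was -0.45, and Trpc5 was highest (1.05 FPKM) in saline 3, where that level was low (2.42), so the values go against a loss of motor neurons. Loss of another neuron type stays open. Repression of Trpc5 after morphine, the subject of the series title, may account for the difference (-0.38 with the length trend removed) and stays open as a hypothesis, since the adjusted p did not pass.

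The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 220 genes, the highest of the others gave 105 (saline 1, saline 2 and morphine 2 against the rest), and 1 of the 10 splits, the real one itself, gave 220 or more. For lists, the real split gave 12, the highest of the others 30, and 7 of the 10, the real one included, gave at least 12. The split with 105 genes and 30 lists is the one that parts the libraries by motor neuron marker level, which points to a structure of the samples besides the treatment.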
